A study of Drosophila melanogaster with 12 samples.

How the data were processed

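The samples were Kc167 cells, a Drosophila melanogaster line of embryonic origin with properties of blood cells. Per the labels' protocols, cells in wells were exposed for 30 min to medium conditioned with Unpaired (UPD), a secreted ligand of the JAK/STAT pathway, or to Mock conditioned medium. Fresh Schneider's medium then took its place, and RNA was taken at 2, 4 or 10 h counted from the start of the exposure. Per the labels, each of the 6 combinations of medium and time has 2 biological replicates, so 12 arrays were hybridised. Total RNA was purified with Trizol followed by a column, and biotinylated cRNA was made from 1 µg of it by the standard Affymetrix procedure, per the labels' protocols. Each array was assigned to its medium, time and replicate number from its title.

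The deposited values are 1 number per probe set and array, and they were used as log2 values, as deposited. No label states the logarithm's base. It was inferred from the values, which ran from −15.82 to 13.96, a span that a linear intensity or a natural logarithm of a scanner reading would not give. The tool that summarised the probes into probe sets, its version and the normalization are not given in the sources used here. The deposited log2 values show part of the scaling: the 6 UPD arrays share a median of 2.327 over all probe sets and the 6 Mock arrays share a median of 2.375. The arrays were therefore scaled to a median within each medium, which places UPD −0.048 from Mock before any gene is considered. Values of dim probe sets have no floor and between 26.2% and 32.0% of each array's values lie below 0, so large log2 differences between values near or below 0 come from dim probe sets. No detection calls were used here.

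The table holds 18952 probe sets. Its 183 Affymetrix control probe sets were left out of all tests, which left 18769. Names came from GEO's platform annotation, updated by gene ID through a RefSeq gene table of assembly Release 6 that was used only for names and genomic gene length. Of the tested probe sets, 13647 have 1 gene, 402 have several and 4720 have none listed; 13544 of those with 1 gene were matched by gene ID. The single-gene probe sets represent 11982 genes. Probe sets with several genes or none were tested and counted but not given a gene name. No coordinates are printed, because the genome build behind the array annotation is not given in the sources used here.

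Tests were made in R 4.3.3 with limma 3.58.1. A linear model with 6 group means was fitted to all 12 arrays, so that every probe set has 6 residual degrees of freedom, followed by empirical Bayes moderation (prior SD 0.57, prior degrees of freedom 1.54). The contrasts were UPD minus Mock at 2, 4 and 10 h, the average of these 3 differences, the moderated F test of their differences between times, and the 3 differences between times within Mock. P-values are two-sided from limma's moderated test and were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, with a threshold of 0.05. Standard errors (SE) are limma's moderated ones; SD is the spread of the 2 arrays of a group. The precision is limited by the number of arrays.

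Gene lists were tested with camera in limma, with its preset correlation between genes, on the probe set with the highest mean of each gene. The adjustment ran over 25 lists and 4 contrasts together. Of 452 symbols in the lists, 449 matched a current gene and 317 were measured by a single-gene probe set. A list of thioester proteins with 2 measured members was not tested. Members were also adjusted over the list alone.

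The contrasts, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. For each UPD contrast the rule takes the 15 largest rises and 10 largest falls past the threshold for which both UPD arrays lie on the same side of both Mock arrays (for the average, with the same sign at all 3 times), with 1 probe set per gene. Where fewer than 5 pass in a direction, it adds the 5 with the smallest p, given as not past the threshold. It also takes 10 genes for the F test, every measured member of the lists of JAK/STAT components and reported JAK/STAT targets, and up to 4 members per contrast of each other list. Genes named from other settings were chosen after their values were seen, and this is said where they appear.

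The alternatives fixed beforehand were quantile normalization, a shift of each array to one median, a filter that keeps the 9384 probe sets above the median mean level, a variance trend with robust moderation, treat with a minimum change of 1.2-fold, a fit on the arrays of the compared times alone, the replicate number as a block, a joint adjustment over the 3 times, and leaving out each array in turn. For the lists they were camera with an estimated correlation, fry, and the mean over all probe sets of a gene. Other alternatives were added after the data had been seen: array weights with the filter, the 8 arrays of 2 and 4 h with and without the filter (and then leaving out each of these 8), quantile normalization with the filter, removal of a trend with gene length and level by loess with a span of 0.3 (from all arrays and from the 8 alone), and the 3′ minus 5′ difference of the Act5C control probe sets as a covariate. The last pair used the 7821 filtered probe sets with known genomic length, 83.3% of the filtered ones.

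The tests were tried on simulated arrays with known changes, placed only in probe sets above the median level. Noise was independent between probe sets, with the measured spread of each group smoothed over probe sets of like level. The recovery of changes in dim probe sets was therefore not tried. With all probe sets and 12 arrays, limma recovered 0% of the 2-fold changes, 16.9% of the 4-fold changes and 59.5% of the 8-fold changes at 2 h, with 10 false calls. At 4 h the shares were 0%, 2.8% and 31.4%, with 3 false calls, and at 10 h 3.1%, 18.3% and 57.8%, with 8 false calls. With the filter and the 8 arrays of 2 and 4 h they were 49.2%, 76.9% and 75.7% at 2 h, with 6 false calls, and 47.5%, 67.6% and 72.9% at 4 h, with 21 false calls. With the filter and 12 arrays at 10 h they were 29.2%, 78.9% and 82.8%, with 258 false calls, because the 10 h arrays vary more than the others with which they share a variance. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.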

Results

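Transcript levels were measured in Kc167 cells, a Drosophila line related to embryonic blood cells, after a 30 min exposure to medium conditioned with the JAK/STAT ligand UPD or to Mock conditioned medium. RNA was taken at 2, 4 and 10 h, with 2 biological replicates for each medium and time, which gives 6 groups and 12 Affymetrix arrays. The number of arrays limits the precision. The deposited log2 values of replicates correlated over probe sets above the median level with r = 0.976 for UPD and 0.98 for Mock at 2 h, 0.969 and 0.965 at 4 h, and 0.953 and 0.921 at 10 h, where the probe sets are not independent replicates. The median replicate SD of probe sets between the 70th and the 90th percentile of levels was 0.063 for UPD and 0.056 for Mock at 2 h, 0.077 and 0.136 at 4 h, and 0.398 and 0.456 at 10 h on the log2 scale. Above the 90th percentile it was 0.046 and 0.090, 0.048 and 0.108, and 0.471 and 0.495. Mock 4 h replicate 2 stood apart in its hybridisation spikes, with a mean of 8.68 against 10.11 to 11.02 on the other arrays, and its highest value was 12.35. The upper quartile of the UPD arrays at 10 h was 6.10 and 6.63, against 7.12 and 6.88 for Mock at 10 h and 7.40 to 7.56 at 2 h. The study followed the response of these cells to the pathway's principal ligand over time, and the comparisons below ask which transcripts differed between UPD and Mock at each time.

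At 2 h after UPD, the level of CG12609 was −2.92 ± 0.29 (SD, n = 2) against 2.51 ± 0.34 in Mock. CG12609 fell by 5.43 ± 0.42 (SE) on the log2 scale, the only call among 18769 probe sets in limma (adjusted p = 0.0363). CG13559 stood at 8.29 ± 0.04 after UPD and 6.74 ± 0.09 after Mock, a 2.94-fold difference. Spn31A, a member of the serpin family of protease inhibitors, stood at 7.06 ± 0.14 and 5.78 ± 0.07, and Galphaf, a G protein alpha subunit, at 5.58 ± 0.15 and 4.25 ± 0.27. The receptor gene dome stood at 8.61 ± 0.02 after UPD and 8.07 ± 0.00 after Mock. CG13559, Spn31A, Galphaf and dome did not pass the threshold at 2 h with all 12 arrays and all probe sets.

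At 2 h, 830 probe sets had an unadjusted limma p under 0.05. CG12609 is dim, with values below 0 after UPD, and Brd and zen2, among the genes with the next smallest p, are dim too. Brd was at 2.19 ± 0.04 after UPD and −2.89 ± 0.59 after Mock (adjusted p = 0.323), and zen2 at −2.31 ± 0.33 and 1.88 ± 0.43 (adjusted p = 0.28). The call of CG12609 was lost with quantile normalization (adjusted p = 0.0542), where 1 other probe set was called higher, with only the 2 h arrays (0.379), with a variance trend and robust moderation (0.0546), with all probe sets of the 8 arrays of 2 and 4 h (0.0884), and without any 1 of 10 of the 12 arrays. These were the 4 arrays at 2 h (0.163 and 0.599 without UPD replicate 1 and 2, 0.441 and 0.264 without Mock replicate 1 and 2), the UPD arrays at 4 h (0.145 each), the Mock arrays at 4 h (0.196 each) and the UPD arrays at 10 h (0.0702 each). Over 36 alternatives the adjusted p of CG12609 ran from 7.56e-05 to 0.717, and 17 of them passed.

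With the 8 arrays of 2 and 4 h and the probe sets above the median level, a setting chosen after the values were seen, 4 probe sets passed at 2 h. CG13559 rose by 1.56 ± 0.09 on the log2 scale (SE; adjusted p = 0.0186 in limma), CG12609 fell by 5.43 ± 0.26 (adjusted p = 0.0115), and 2 probe sets without a listed gene were higher. The adjusted p of CG13559 at 2 h ran from 0.000966 to 1 over 36 alternatives. Its call in this setting was lost without any of the arrays at 2 h (0.195 and 0.331 without UPD replicate 1 and 2, 0.247 and 0.176 without Mock replicate 1 and 2) and without either UPD array at 4 h (0.0873). The count was 1 without either Mock array at 2 h and 2 without any 1 of the 4 UPD arrays. On simulated arrays this setting made 6 false calls at 2 h.

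At 4 h Galphaf was at 6.45 ± 0.07 after UPD and 3.73 ± 0.22 after Mock (SD, n = 2), a 6.57-fold difference. Spn31A was at 7.16 ± 0.03 against 5.07 ± 0.03 (4.26-fold), CG13559 at 8.29 ± 0.06 against 6.37 ± 0.09 (3.79-fold) and CG4793 at 7.36 ± 0.08 against 5.63 ± 0.11 (3.31-fold). The small heat shock protein gene Hsp27 was at 8.94 ± 0.07 against 7.47 ± 0.10, and dome at 8.57 ± 0.04 against 7.65 ± 0.01 (1.89-fold). HDAC11, a histone deacetylase gene, was at 0.27 ± 0.04 against 2.40 ± 0.06.

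In limma with all arrays and probe sets, 0 probe sets passed at 4 h, with 757 at an unadjusted p under 0.05. The differences of Galphaf (2.72 ± 0.38 on the log2 scale, SE; adjusted p = 0.419), Spn31A (2.09 ± 0.34; 0.59), CG4793 (1.73 ± 0.31; 0.6) and HDAC11 (−2.13 ± 0.35; 0.59) were therefore not past the threshold. The smallest adjusted p, 0.206, belonged to hlk, at −4.85 ± 0.94 after UPD and 0.41 ± 0.18 after Mock, while the other probe set of hlk differed by −0.87 on the log2 scale. With a variance trend and robust moderation 6 probe sets were called, all higher, and treat and quantile normalization called 0. Whether responses differed between 2 and 4 h was tested in the same model, and 0 probe sets passed, with 777 at an unadjusted p under 0.05.

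With the 8 arrays of 2 and 4 h and the probe sets above the median level, chosen after the values were seen, 15 probe sets passed at 4 h, 12 higher and 3 lower. In this setting Spn31A rose by 2.09 ± 0.10 (SE) on the log2 scale, CG13559 by 1.92 ± 0.09, Galphaf by 2.72 ± 0.18, CG33459 by 1.98 ± 0.14, CG4793 by 1.73 ± 0.12, Hsp27 by 1.47 ± 0.11, CG4822 by 1.42 ± 0.12, CG17660 by 1.19 ± 0.11, dome by 0.92 ± 0.07 and CG1628 by 0.89 ± 0.08. HDAC11 fell by 2.13 ± 0.09. The limma adjusted p was 0.00799 for Spn31A and CG13559, 0.0213 for Galphaf and 0.0302 for dome. Over 36 alternatives it ran from 0.00121 to 1 for Spn31A and CG13559, from 0.00148 to 1 for Galphaf and from 0.0302 to 1 for dome. The count depended on single arrays. It was 0 without UPD 2 h replicate 1, UPD 2 h replicate 2 or UPD 4 h replicate 2, 1 without Mock 4 h replicate 1, 4 without either Mock array at 2 h, 12 (3 higher, 9 lower) without UPD 4 h replicate 1, and 79 (75 higher, 4 lower) without Mock 4 h replicate 2. After removal of a trend with gene length it was 24, 19 higher and 5 lower. On simulated arrays the setting made 21 false calls at 4 h.

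**Figure D1:**
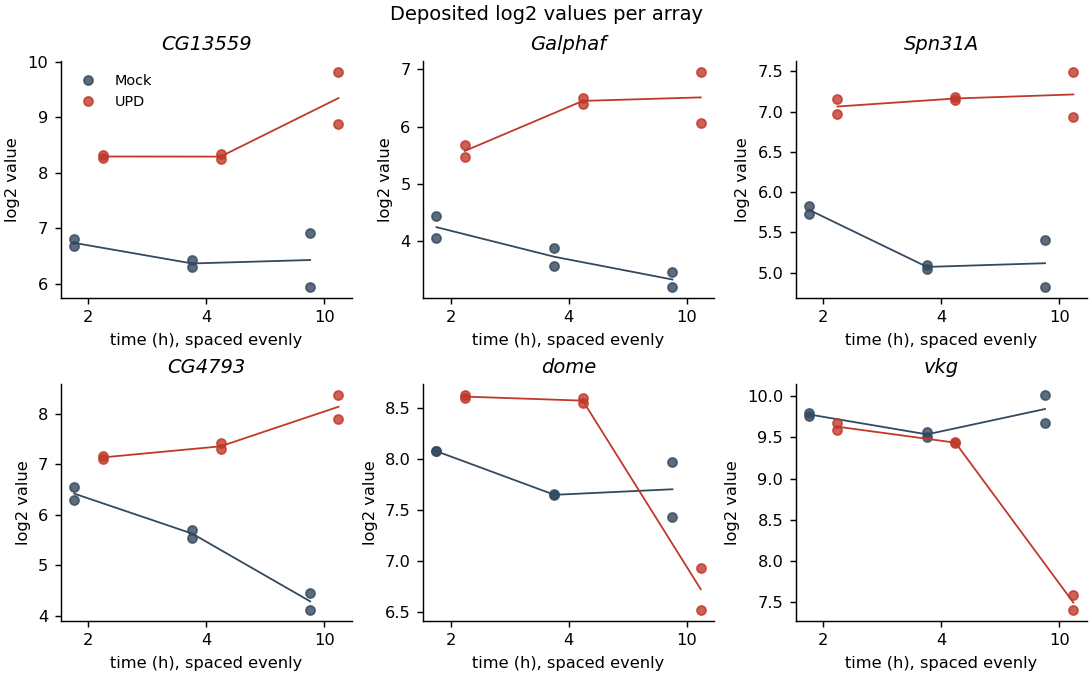
Deposited log2 values of CG13559, Galphaf, Spn31A, CG4793, dome and vkg on each array at 2, 4 and 10 h, spaced evenly, with points for arrays and lines joining the group means of UPD and Mock. CG13559, Galphaf, Spn31A and CG4793 lie above Mock at each time, while dome lies above Mock at 2 and 4 h and below it at 10 h, where the replicates spread more.

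Averaged over 2 and 4 h in the same 8-array setting, again chosen after the values were seen, 26 probe sets passed, 19 higher and 7 lower. CG13559 rose by 1.74 ± 0.07 (SE) on the log2 scale (limma adjusted p = 0.00255) and Spn31A by 1.69 ± 0.07 (0.00261), and both passed whichever 1 of the 8 arrays was left out, with a highest adjusted p of 0.0482 each. Over 11 fits of these arrays, with and without the filter, the adjusted p of this average ran from 0.00255 to 0.0893 for CG13559 and from 0.00261 to 0.0893 for Spn31A. Galphaf rose by 2.02 ± 0.13, CG4793 by 1.22 ± 0.09, CG4822 by 1.21 ± 0.08, CG4080 by 1.00 ± 0.08, Hsp27 by 0.99 ± 0.08, dome by 0.73 ± 0.05, Nepl3 by 0.64 ± 0.06 and drongo by 0.64 ± 0.06, and syd fell by 1.94 ± 0.19. The count was 5 without UPD 2 h replicate 1, UPD 2 h replicate 2 or Mock 2 h replicate 1, 4 without Mock 2 h replicate 2, 8 and 9 without UPD 4 h replicate 1 and 2, and 17 without Mock 4 h replicate 1. With all probe sets of the 8 arrays it was 0, and after removal of a trend with gene length from them 44, 33 higher and 11 lower.

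At 10 h, 199 probe sets passed in limma with all arrays and probe sets, 20 higher and 179 lower after UPD. Among the rises, CG4793 stood at 8.14 ± 0.33 after UPD and 4.29 ± 0.24 after Mock (SD, n = 2), Galphaf at 6.51 ± 0.63 and 3.34 ± 0.18, CG13559 at 9.34 ± 0.67 and 6.43 ± 0.68, and Spn31A at 7.21 ± 0.40 and 5.12 ± 0.42. CG4793 rose by 3.85 ± 0.31 (SE, limma adjusted p = 0.0167), Galphaf by 3.17 ± 0.38 (0.027), CG13559 by 2.92 ± 0.44 (0.0399) and Spn31A by 2.10 ± 0.34 (0.0472) on the log2 scale. All SE at 10 h share a variance with the less variable arrays at 2 and 4 h, so they and the adjusted p may be too small. Sid, a gene for a stress-induced DNase, was above Mock by 3.40 ± 0.41 and CG6357 by 2.80 ± 0.35. For CG4793, Sid and CG6357 part of the difference lay in Mock, which was lower at 10 h than at 2 h. At 2 h CG4793 stood at 7.14 after UPD and 6.42 after Mock, and CG6357 at 7.73 and 7.61. CG6357 stood at 8.74 and 5.94 at 10 h. Sid stood at 5.70 and 5.71 on the UPD arrays at 2 h and 5.97 and 6.43 at 10 h. On the Mock arrays Sid stood at 5.52 and 5.10, then at 3.29 and 2.31. The dim genes ci and net, with low mean levels over the arrays, were higher than Mock by 4.85 and 5.18. After UPD they stood at 2.29 and 2.33, below their UPD levels at 2 h (2.68 and 3.82), and Mock at 10 h was at −2.56 and −2.85. The values of CG4793 are from its brightest probe set; its other probe sets, at mean levels of 3.07 and −1.03, differed by 1.28 and 1.91 and did not pass.

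Among the falls at 10 h, HERC2, a member of the HERC ubiquitin ligase family, fell by 8.53 ± 1.18 (SE) on the log2 scale, from 6.45 ± 1.11 in Mock to −2.08 ± 2.88 after UPD. The RFX transcription factor gene Rfx fell by 6.44 ± 0.57, xmas-1 by 6.43 ± 0.64 and rempA, an intraflagellar transport gene, by 4.91 ± 0.58. After UPD Rfx was at −2.80 ± 0.27, xmas-1 at −2.02 ± 0.92 and rempA at 0.09 ± 1.32. Like that of HERC2 these are dim values without detection calls, so the sizes of these 4 falls are uncertain. Type IV collagen genes fell at higher levels: vkg stood at 7.50 ± 0.13 after UPD against 9.84 ± 0.24 in Mock and Col4a1 at 7.87 ± 0.45 against 10.20 ± 0.47. The limma adjusted p was 0.0331 for HERC2, 0.0172 for Rfx, 0.027 for rempA and vkg, and 0.0416 for Col4a1.

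Of the calls at 10 h, 89.9% were lower, and with quantile normalization 578 were called, 172 higher and 406 lower (70.2%). The median difference at 10 h over probe sets above the median level was −0.41 on the log2 scale as deposited and −0.01 after quantile normalization. Both vkg and Col4a1 lay further from Mock than that median by more than their SE. With a fit on the 10 h arrays alone 0 probe sets passed, with 1403 at an unadjusted p under 0.05, and a joint adjustment over the 3 times left 6. Leaving out any of the 4 arrays at 2 h or either UPD array at 4 h left 0 calls, and leaving out either Mock array at 4 h left 10. Leaving out UPD 10 h replicate 1 and 2 and Mock 10 h replicate 1 and 2 left 76, 315, 6 (5 of them higher) and 468. CG4793 kept its call without any 1 of 6 arrays (the Mock arrays at 4 h and the 4 arrays at 10 h), Galphaf without UPD 10 h replicate 1 or 2 or Mock 10 h replicate 2, CG13559 without UPD 10 h replicate 1 or Mock 10 h replicate 2, and Spn31A lost its call without each of the 12 (0.0518 to 0.124). The 3′ minus 5′ difference of the Act5C control probe sets was 1.37 and 1.25 on the UPD arrays at 10 h, 1.15 and 1.14 on the Mock arrays at 10 h and 0.71 to 0.89 on the arrays at 2 h. That of Gapdh at 10 h was 1.90 and 2.22 for UPD and 2.26 and 2.53 for Mock, and that of eIF4a 1.04 and 0.93 for UPD and 0.73 and 1.21 for Mock. Among probe sets above the median level with known gene length, the median difference at 10 h was −0.11 for the third with the shortest genes, −0.59 for the middle and −0.80 for the third with the longest.

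**Figure D2:**
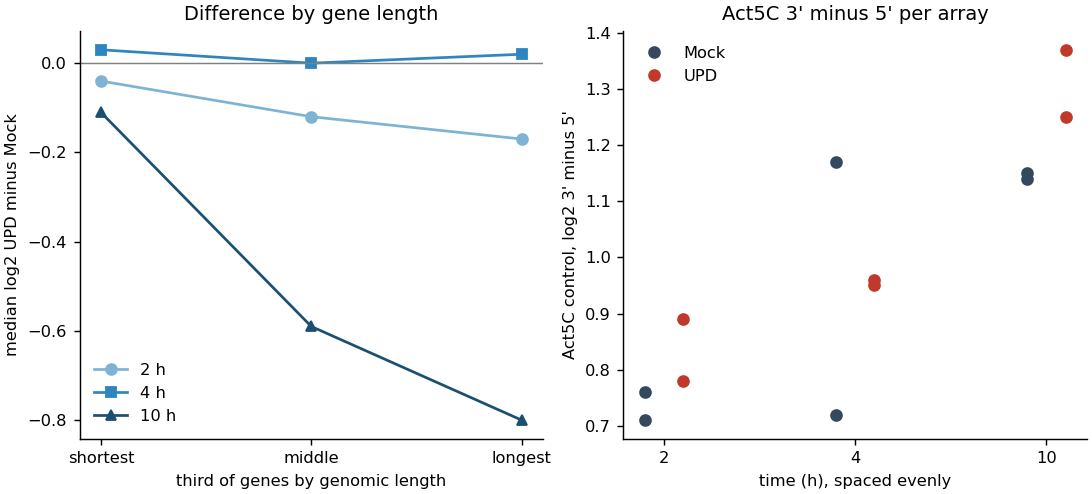
Left, the median UPD minus Mock difference (log2) of probe sets above the median level in 3 equal classes of genomic gene length at 2, 4 and 10 h; right, the 3′ minus 5′ difference (log2) of the Act5C control probe sets on each array. The 10 h medians run from −0.11 for short genes to −0.80 for long ones, and the UPD arrays at 10 h have the highest Act5C differences, 1.25 and 1.37.

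Averaged over the 3 times, CG4793 was 2.10 ± 0.18 (SE) above Mock on the log2 scale, Galphaf 2.41 ± 0.22, Spn31A 1.82 ± 0.20 and CG13559 2.13 ± 0.25, with UPD above Mock at each time. Oatp58Db was at −1.56 ± 0.21 relative to Mock. None of the 18769 probe sets passed in limma. The adjusted p was 0.0565 for CG4793 and Galphaf, 0.0724 for Spn31A, 0.0867 for CG13559 and 0.139 for Oatp58Db, and 2024 probe sets had an unadjusted p under 0.05. With the filter on low values, fixed beforehand, 152 probe sets passed, 18 higher and 134 lower, and Galphaf (adjusted p = 0.00168), CG4793 (0.00168), Spn31A (0.00376) and CG13559 (0.00644) rose. Hsp27 rose by 1.15 ± 0.13, CG4822 by 1.08 ± 0.15 and Rfx fell by 2.33 ± 0.29 in that setting, where these 3 were chosen after the values were seen. The averaged fall of Rfx came mostly from 10 h, since its UPD and Mock arrays overlapped at 2 and 4 h. Quantile normalization called 27 probe sets, 17 higher and 10 lower, and a variance trend with robust moderation called 351, 34 higher and 317 lower. The adjusted p of the average over the 3 times ran over 23 alternatives from 1.2e-11 to 0.655 for CG4793, from 7.53e-09 to 0.655 for Galphaf and Spn31A, and from 2.17e-12 to 0.655 for CG13559. With all probe sets the count was 4 without UPD 10 h replicate 1, 1 without Mock 10 h replicate 1 and 7 without Mock 10 h replicate 2.

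Differences of the UPD response between times were tested with limma's F test. The smallest adjusted p, 0.2, belonged to CG12609, which passed at 2 h, and to hlk, which passed at no time, followed by Rfx and zen2 (0.242 each) and pyd (0.254). For dome the differences were 0.53, 0.92 and −0.98 at 2, 4 and 10 h, with an adjusted F p of 0.389. No probe set passed (0 of 18769), with 1671 at an unadjusted p under 0.05. The filter on low values gave 88, a variance trend with robust moderation 299 and quantile normalization 4, and 1 passed without Mock 10 h replicate 1.

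The arrays given Mock medium show how levels differed with time without UPD. With all probe sets limma called 0 in Mock at 4 h against 2 h, 0 at 10 h against 2 h and 0 at 10 h against 4 h, with 930, 2704 and 1084 at an unadjusted p under 0.05. With the filter on low values 43 probe sets passed at 10 h against 2 h, 3 higher and 40 lower, and the genes named from them were chosen after the values were seen. The cytochrome P450 gene Cyp6a20 fell by 2.62 ± 0.26 (SE) on the log2 scale, the insulin receptor gene InR fell by 2.12 ± 0.32, Sid fell by 2.51 ± 0.36 and CG4793 fell by 2.13 ± 0.25. The difference between 10 and 2 h in Mock fell with gene length (Spearman −0.37 across genes, which are not independent), and the Act5C difference was 1.15 and 1.14 on the Mock arrays at 10 h and 0.76 and 0.71 at 2 h. With the Act5C difference as a covariate, chosen after the values were seen, limma called 0 probe sets (220 at an unadjusted p under 0.05), and 12 passed after removal of the trend with gene length. The slope of the covariate comes from differences within groups, mostly that between the Mock arrays at 4 h (1.17 and 0.72). The 0 calls therefore cannot tell whether the Act5C difference accounts for the change in Mock. A variance trend with robust moderation called 845 at 10 h against 2 h and 17 at 10 h against 4 h. Without Mock 10 h replicate 2 the counts with all probe sets were 84 and 10, without Mock 10 h replicate 1 they were 6 and 3, and without either UPD array at 4 h 1 passed at 10 h against 2 h. The median Mock difference above the median level was −0.33 at 4 h and −0.41 at 10 h against 2 h, and 0.00 and 0.03 after quantile normalization. In the 8-array setting chosen after the values were seen, 1 probe set differed between 4 and 2 h, 2 did without Mock 4 h replicate 1, 3396 (3351 lower) did without Mock 4 h replicate 2, and 0 without any other.

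The JAK/STAT components form a list of 18 symbols with 15 measured members, fixed beforehand like all lists. Neither hop nor Socs36E is among the measured members of this list or of the reported targets, so these tests do not cover them. Over all genes and adjusted over the list alone, 0 members passed at 2 h and 0 at 4 h. At 4 h dome stood at 0.92 ± 0.31 (SE) on the log2 scale, Ptp61F, a phosphatase gene, at 0.47 ± 0.33 and Stat92E, the transcription factor of the pathway, at 0.18 ± 0.36. At 10 h camera called the list lower (median −0.71, 2 of 15 members above 0, adjusted p = 0.0409). With an estimated correlation camera gave an adjusted p = 0.943 (0.0866 unadjusted), and fry gave an adjusted p = 0.00925. Over all genes 0 members passed at 10 h, and 6 were lower adjusted over the list alone: Socs16D at −2.51 ± 0.49, et at −1.96 ± 0.37, BRWD3 at −1.73 ± 0.31, Hrs at −1.39 ± 0.34, ken at −1.13 ± 0.30 and dome at −0.98 ± 0.31. Stat92E was at −0.09 ± 0.36. The call of the list was lost after removal of the trend with gene length (adjusted p = 0.604), with the filter on low values (0.134), with quantile normalization (0.0727) and without 9 of the 12 arrays, with the highest adjusted p, 0.295, without Mock 10 h replicate 2, and dome was at −0.11 after that removal.

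**Figure D3:**
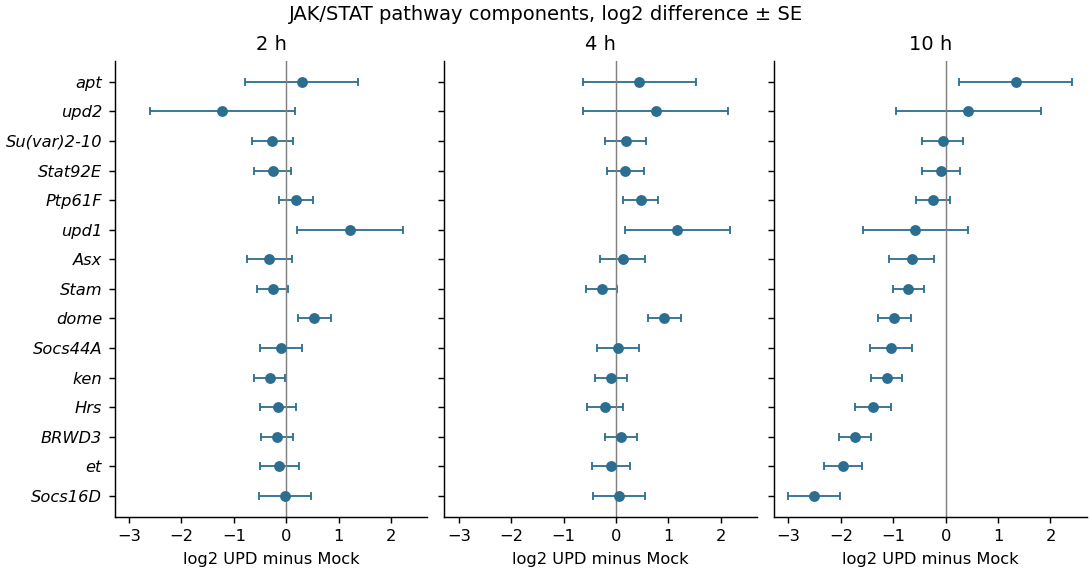
UPD minus Mock difference (log2, with SE from limma, 12 arrays) of the 15 measured JAK/STAT components at 2, 4 and 10 h. At 10 h 13 of the 15 lie below 0, while dome lies above 0 at 2 and 4 h.

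The list of reported JAK/STAT targets has 24 symbols and 16 measured members. At 4 h 11 of them lay above 0, with chinmo at 0.90 ± 0.54 (SE), Imp at 0.60 ± 0.35, zfh1 at 0.42 ± 0.48 and vir-1 at 0.33 ± 0.46 on the log2 scale, and 0 passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.08 at 4 h (0.00904 with the filter on low values, 0.943 with an estimated correlation) and 0.239 at 10 h. At 10 h 1 member was lower over all genes, Col4a1, and 7 were lower adjusted over the list alone, among them Tep4 at −1.33 ± 0.33, wdp at −1.26 ± 0.35 and lama at −0.91 ± 0.29. The Turandot list, stress-induced secreted peptides, had a smallest adjusted p of 0.466.

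At 4 h camera called 3 lists higher after UPD. Of the 10 members of the list of MAPK and EGFR targets, 8 lay above 0 (median 0.37, adjusted p = 0.0131), with aos, a secreted inhibitor of the EGF receptor, at 0.71 ± 0.29 (SE), edl at 0.53 ± 0.31, kek1 at 0.39 ± 0.30 and Mkp3, a MAPK phosphatase gene, at 0.35 ± 0.33. Of 19 genes of ribosome biogenesis, 18 lay above 0 (median 0.23, adjusted p = 0.0131), with Polr1B at 0.43 ± 0.34, Nop60B at 0.35 ± 0.35 and ppan at 0.33 ± 0.32. All 17 ribosomal protein genes lay above 0 (median 0.48, adjusted p = 3.96e-05). No member of the 3 lists passed over all genes (0) or adjusted over the list alone (0), and each list had an adjusted p = 0.943 with an estimated correlation. Without Mock 4 h replicate 2, the array with the low spikes, the adjusted p was 0.205 for the MAPK and EGFR targets, 0.213 for ribosome biogenesis and 0.791 for the ribosomal proteins. Their medians were then 0.41, 0.24 and 0.00, with 9 of 10, 17 of 19 and 9 of 17 members above 0. The first 2 lists were still called without 9 of the 12 arrays and the third without 11. Quantile normalization gave a median of 0.03 for the ribosomal proteins (adjusted p = 0.642).

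At 10 h camera also called 3 further lists lower, on arrays whose UPD group had the lower upper quartiles, higher Act5C differences and lower Gapdh differences given above. Of 18 measured plasmatocyte markers, genes of the main blood cell type of the fly, 3 lay above 0 (median −1.28, adjusted p = 0.0399). Over all genes 4 fell: vkg by 2.35 ± 0.28 (SE), Col4a1 by 2.33 ± 0.36, the papilin gene Ppn by 2.33 ± 0.32 and the peroxidasin gene Pxn by 1.87 ± 0.31, all products of the extracellular matrix. Adjusted over the list alone 7 were lower, with drpr at −1.39 ± 0.28, Pvr at −1.32 ± 0.30 and ush at −1.04 ± 0.32 added, while SPARC was at −0.03. Of 19 genes of the G1 to S transition 0 lay above 0 (median −0.67, adjusted p = 0.0131), with the origin licensing genes Orc1 at −1.29 ± 0.36 and Cdc6 at −1.31 ± 0.41 and the cyclin gene CycE at −1.21 ± 0.36. Of these, 0 passed over all genes and 0 adjusted over the list alone. The unfolded protein response list of 16 members was lower (median −0.70, adjusted p = 0.0409), 0 members passing over all genes and 5 adjusted over the list alone, among them the chaperone gene Hsc70-3 at −1.15 ± 0.34 and the kinase genes Ire1 at −1.21 ± 0.34 and PEK at −1.20 ± 0.34. Each of these lists had an adjusted p = 0.943 with an estimated correlation. After removal of the trend with gene length the adjusted p was 0.0856 for the plasmatocyte markers, 0.575 for G1 to S and 0.183 for the unfolded protein response. With the filter on low values the last pair were not called (0.134 and 0.262), nor G1 to S with quantile normalization (0.102). The plasmatocyte call was lost without 8 of the 12 arrays (highest adjusted p 0.295, without Mock 10 h replicate 2), the unfolded protein response without 9 (0.185, without UPD 10 h replicate 1) and G1 to S without Mock 4 h replicate 2 (0.0573).

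For the average over the 3 times, camera called the ribosomal proteins higher (adjusted p = 0.0473) and the G1 to S genes (0.042) and plasmatocyte markers (0.0399) lower, each at an adjusted p = 0.943 with an estimated correlation. For the average of the 8 arrays of 2 and 4 h, added after seeing the data, camera gave 0.00237, 0.337 and 0.668. The plasmatocyte median was −0.15 at 2 h and −0.08 at 4 h, against −1.28 at 10 h. Over all genes 0 members of these lists passed, and adjusted over the list alone 5 plasmatocyte markers were lower, with vkg at −0.87 ± 0.16 (SE). These calls were lost without most single arrays, with the highest adjusted p of 0.866 for the ribosomal proteins without Mock 4 h replicate 2, 0.118 for G1 to S without UPD 2 h replicate 2 and 0.276 for the plasmatocyte markers without Mock 10 h replicate 2. With quantile normalization the ribosomal proteins were at 0.732, with the filter on low values G1 to S was at 0.196, and after removal of the trend with gene length the ribosomal proteins, G1 to S and plasmatocyte markers were at 0.917, 0.262 and 0.0855. The 25 lists and 4 contrasts made 100 tests, of which 10 passed, and 18 lists had no call. The smallest adjusted p of each was 0.0685 for the FoxO and nutrient list, 0.08 for reported JAK/STAT targets, Imd and Toll targets and lamellocyte markers, and 0.0918 for cytoskeleton and adhesion. It was 0.127 for glycolysis, 0.142 for apoptosis and for muscle markers, 0.207 for G2 to M genes, heat shock genes and germline markers, 0.235 for ecdysone response, 0.247 for JNK targets, 0.37 for crystal cell markers, 0.466 for the Turandot list, 0.497 for Notch targets and for neuron and glia markers, and 0.661 for fat body markers, whose median (0.08) and mean (−0.18) at 4 h differ in sign.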

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

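The tests of gene length and of the scaling in this part were chosen only after the 10 h result was seen. The UPD minus Mock difference of dome was −0.98 on the log2 scale at 10 h, with both UPD arrays below both Mock arrays, and 0.53 and 0.92 at 2 and 4 h, with both above. The difference of dome between times did not pass limma's F test (adjusted p = 0.389; 0.0705 with the filter on low values). The heat shock co-chaperone gene DnaJ-1 was at −0.84 at 2 h, 0.15 at 4 h and −0.50 at 10 h, with UPD on different sides of Mock, and this did not pass the F test either (adjusted p = 0.677; 0.288 with the filter). In the control probe sets, which were left out of the tests and of which Act5C served as a covariate in 1 alternative, the 3′ minus 5′ difference of Act5C was higher on both UPD arrays than on both Mock arrays at 2 h (mean 0.84) and at 10 h (mean 1.31, against 1.15 for Mock), and that of Gapdh was higher at 4 h (mean 2.25). In the other direction, that of Gapdh was lower on both UPD arrays at 10 h (1.90 and 2.22, against 2.26 and 2.53 for Mock), and that of eIF4a at 2 h (0.58 and 0.66, against 0.74 and 0.68). With 2 arrays a group, 33.3% of such sets of values separate in one direction or the other by chance.

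Far more probe sets were lower than higher after UPD at 10 h, 179 against 20. With every array shifted to one median 98 of 111 calls (88.3%) were lower, which argues against the different medians of UPD and Mock arrays as the cause. Whether the authors' scaling to a median caused part of the excess cannot be told apart from a response to UPD, since quantile normalization left 70.2% lower but itself sets the distributions of the arrays equal. The same holds for RNA integrity or labelling that depends on gene length: above the median level the 10 h difference fell with gene length (Spearman −0.36 across genes, which are not independent; −0.19 at the lowest levels, −0.48 at the highest), as did UPD against Mock at 2 h (−0.28) and, without UPD, Mock at 4 h (−0.25) and 10 h (−0.37) against 2 h, while the share of lower calls after removal of the trend, 59.0%, is partly set by the removal. The deviation of the arrays from the mean of each probe set correlated with gene length at −0.48 and −0.50 for UPD and at −0.26 and 0.25 for Mock at 10 h. It was 0.11 and 0.43 for Mock 4 h replicates 1 and 2, against 0.45 and 0.52 for Mock at 2 h. The Mock trend at 4 h thus rested mostly on replicate 1. The Act5C and Gapdh differences went opposite ways at 10 h, and a response to UPD that falls on long genes stays open and untested.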

How the results depend on the processing

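Settings other than those fixed beforehand are named as added after seeing the data. Counts of passing probe sets are given where they differed by over 1.5 times from limma on all arrays and probe sets (2 h 1, 4 h 0, 10 h 199, average 0, F test 0, Mock contrasts 0, lists 10); the cause was not tested unless stated. Quantile normalization gave 578 at 10 h, 27 for the average and 4 for the F test. A shift to one median gave 111 at 10 h and 3 for the average. The filter on low values, which tests fewer and less noisy probe sets, gave 1804 (86 higher) at 10 h, 152 for the average, 88 for the F test, and for Mock 43 at 10 against 2 h and 1 at 10 against 4 h. On simulated arrays this filter made 258 false calls at 10 h, against 8 with all probe sets. The 10 h arrays vary more than those with which they share a variance, so these counts may be too high where 10 h enters. A variance trend with robust moderation gave 4, 6 and 1899 at 2, 4 and 10 h, 351 for the average, 299 for the F test, and 845 and 17 for these Mock contrasts. Treat gave 89 at 10 h, and a joint adjustment 6. Fits on the compared times alone, with fewer arrays, gave 0 at 2 h, 0 at 10 h and 1 in Mock at 10 against 2 h. With the replicate number as a block there were 0 calls at 2 h, 0 at 10 h and 1 list. Over probe sets above the median level, deviations of arrays with the same number correlated at −0.04, −0.03 and −0.05 at 2, 4 and 10 h. That compares UPD with Mock within each time only, so a batch carried by the replicate number is not excluded. For the lists an estimated correlation gave 0 calls, fry 3 and the mean over probe sets 5. Those of fry, all lower, were the JAK/STAT components at 10 h (adjusted p = 0.00925) and the plasmatocyte markers at 10 h (0.00732) and averaged (0.022). At 10 h the median of all probe sets above the median level was −0.41 too. The other list settings stayed within 1.5 times in number but not in which lists: quantile normalization and the filter gave 11 each, of which 6 were among the 10. Added after seeing the data, removal of the length trend gave 10 (8 higher, 2 lower), 3 of them among the 10, and the 8 arrays of 2 and 4 h gave 8 (7 higher, 1 lower), 4 of them counted among the 10. Among those 4, the ribosomal proteins for the average are not a like match, since their average there covers only 2 and 4 h. Added after seeing the data, array weights with the filter gave 88, 13 and 16 at 2, 4 and 10 h, 33 for the average and 3 for the F test. The 8 arrays of 2 and 4 h with the filter gave 4 and 15 at 2 and 4 h, 26 for their average, 1 for Mock at 4 against 2 h and 2 for the difference between times. Quantile normalization with the filter gave 3, 9 and 2492 (1045 higher) at 2, 4 and 10 h, 677 for the average, 5 for Mock at 10 against 2 h and 409 for the F test. The filter with known gene length gave 1730 at 10 h, 258 for the average, 41 for Mock at 10 against 2 h and 93 for the F test. Removal of the length trend gave 5, 10 and 1788 (733 higher) at 2, 4 and 10 h, 472 for the average, 317 for the F test, and in Mock 1 at 4 against 2 h, 12 at 10 against 2 h and 10 at 10 against 4 h. In the 8 arrays alone this removal gave 6 and 24 at 2 and 4 h and 44 for their average. The Act5C covariate gave 833 at 10 h, 13 for the average and 2 for the F test. Leaving out single arrays, in the full or the 8-array setting, gave 0 to 5 at 2 h, 0 to 79 at 4 h, 0 to 468 at 10 h, 0 to 36 for the average, 0 to 16 for the F test, 0 to 3396, 0 to 84 and 0 to 10 for Mock at 4 against 2, 10 against 2 and 10 against 4 h, and 0 (without Mock 4 h replicate 2) to 13 (without Mock 10 h replicate 1) lists. The highest of these counts for the average and the F test belong to the 8-array setting. Its average and its difference between times cover only 2 and 4 h, so they are not those of the full fit. A lone array was assumed to vary like the other groups. A part of the genes named here was refitted in each setting. Of 1385 such refits, 671 planned and 374 added ones kept their side of the threshold, 28 and 150 newly passed it, 148 and 14 lost it, and none changed direction. Other named genes, such as Col4a1, ci, net and Oatp58Db, are not in this tally. Pseudocounts were not run because the values are on a log2 scale, a fit on the compared times alone was not run for the average and the F test, and treat was not run for the F test. The arrays have no detection calls here, so dim probe sets, with values near or below 0, cannot be set against background.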

Other observations

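The tests of gene length, of separate processing and of single arrays in this part were chosen only after the results were seen, as was the use of the filter and of the 8 arrays in the counts over other splits. At 2 h the heat shock genes Hsp68 and DnaJ-1 stood at −1.15 ± 0.34 and −0.84 ± 0.29 (SE) on the log2 scale relative to Mock (limma, adjusted over the list alone 0.0759 and 0.0772), whereas Hsp27 stood at 0.50 ± 0.29. At 4 h Hsp68 was at −0.01 and Hsp27 at 1.47 ± 0.29, the only member of the heat shock list that passed adjusted over the list alone (0.0082), with 0 members over all genes and a smallest camera adjusted p of 0.207. In the FoxO and nutrient list 1 of 10 members lay above 0 at 2 h (median −0.47, camera adjusted p = 0.0685), with Sesn at −0.75 ± 0.31, Pepck1 at −0.55 ± 0.31 and bmm, a lipase gene, at −0.53 ± 0.43. The camera adjusted p ran from 0.00156 after removal of the length trend to 0.943 with an estimated correlation. That sign was not particular to this list. At 2 h 0 of 17 ribosomal protein genes (median −0.09) and 0 of 13 G2 to M genes (median −0.15) lay above 0, though 7 of 10 MAPK and EGFR targets did. Of the 9384 probe sets above the median level, 4160 had both UPD arrays below both Mock arrays and 637 had both above. Their median difference was −0.11.

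At 4 h 3 members of the list of Imd and Toll targets were lower adjusted over the list alone (0.0176 each) and 0 over all genes: the peptide genes CecB at −2.02 ± 0.45 (SE) and Mtk at −2.66 ± 0.62, and PGRP-SB1, a dim gene, at −4.29 ± 0.87. Camera gave the list an adjusted p of 0.0999 there (0.0348 with the filter, 0.943 with an estimated correlation). At 10 h 12 of 18 members lay above 0 (median 0.42). The camera adjusted p was 0.08, with 0.0101 with the filter, 0.0343 with quantile normalization, 0.219 after removal of the length trend and 0.943 with an estimated correlation. In Mock alone 0 of 18 lay above 0 at 10 against 2 h (median −1.11). That sign was not particular to this list. The median of all probe sets above the median level was −0.41 there, and 0 of 19 ribosome biogenesis genes (median −0.49) and 0 of 10 FoxO and nutrient genes (median −1.06) lay above 0. The difference of the list between times was not tested. Of the lamellocyte markers, genes of a blood cell type formed on wounding or parasitism, 4 were lower at 10 h adjusted over the list alone (camera adjusted p = 0.08): ItgaPS5 at −1.74, rhea at −1.65, Tig at −1.41 and cher at −1.39. In the cytoskeleton and adhesion list rhea and cher, shared with the former list, and LanB1 at −1.37 were lower adjusted over the list alone (camera adjusted p = 0.0918). After removal of the length trend the camera adjusted p was 0.865 for the lamellocyte markers and 0.842 for the cytoskeleton list, which then leaned higher.

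Of 19 probe sets that rose after UPD over 2 and 4 h, 17 could be tested after removal of the trend with gene length from the 8 arrays. Of these, 94.1% were called higher (16 of 17, median 0.99 before and 1.01 after on the log2 scale). The trend itself was small above the median level. From short to long genes the class medians of UPD minus Mock were −0.04, −0.12 and −0.17 at 2 h. At 4 h they were 0.03, 0 and 0.02. Removing so small a trend could hardly undo these rises, so the kept calls cannot decide whether gene length is their source. The medians show only that the average trend with gene length was too small to account for the rises. At 10 h 13 of the 19 lay above 0 with the filter, 8 of them called and dome called lower (−0.98), and after removal of the trend, which itself lifts long genes at 10 h, 16 of 17 did, 15 of them called. Separate processing of UPD and Mock arrays cannot be told apart from a response to UPD, a hypothesis that stays open, because all arrays of a medium share it. The correlation of differences at 2 and 4 h over the lowest 40% of levels, 0.0016, rests on dim, noisy values (median replicate SD 1.19). Above the median level it was 0.03 (0.10 and 0.12 with those at 10 h), in a set too wide to show a difference in a few genes. In a fit with terms for time and medium only, the real split of the 8 arrays gave 5 calls and the highest other 1. Of 34 splits 1, the real one itself, was thus as large. A split with that 1 call set the replicate 1 arrays against the replicate 2 arrays. The setting was chosen after its calls were seen and this fit is not the one behind the 19 rises, so chance is not excluded for these. With 12 arrays and the filter it was 2 of 100 (5 real, 16 in a split that sets the 4 arrays at 2 h, Mock 4 h replicate 1 and Mock 10 h replicate 2 against the rest), which points to a structure of the arrays, so a grouping other than the medium stays open, and with all probe sets 100 of 100 (0 real, 1 at most in another), which has no bearing on chance because every split reaches 0.

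Of the lists that were higher at 4 h, the ribosomal proteins relied on Mock 4 h replicate 2, the array with low spikes: without it 0.2% of their median difference was left (0.48 to 0.00), so the values of that array may account for this call. For the MAPK and EGFR targets 111.2% was left (0.37 to 0.41, 9 of 10 members above 0), so the size of their median difference did not rest on that array. Camera sets a list against all other genes, so a kept median does not clear that array as a source of the call. The call was lost without that array and without either UPD array at 4 h, but not without Mock 4 h replicate 1. For ribosome biogenesis 106% was left (0.23 to 0.24, 17 of 19 above 0), and its call was lost and kept without the same arrays at 4 h. At 10 h the MAPK and EGFR targets lay the other way (median −0.74, 2 of 10 above 0, camera adjusted p = 0.253, 0.842 after removal of the length trend), with 3 lower adjusted over the list alone, and the difference of the list between times was not tested. A response of these targets to UPD at 4 h is a hypothesis that remains open.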
